A study of Mus musculus with 425 samples.

How the data were processed

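Per the labels, small RNA of sperm and epididymis, mRNA of epididymis and mRNA of single preimplantation embryos of mice were sequenced. The males carried floxed Dgcr8, the partner of Drosha in the nuclear step of miRNA processing, and a Cre active in germ cells (Stra8-iCre) or in the epididymis (Defb41-iCre). Males homozygous for the floxed allele are called cKO here, and heterozygous Cre carriers are called control. Per the labels' protocols, small RNA was isolated from a gel and made into libraries with an Illumina TruSeq small RNA kit, tissue mRNA libraries were made with a stranded Illumina kit, and embryo libraries with Nextera XT after egg donors of strain FVB/NJ were used. Per the labels, embryos of cKO fathers of the Defb41 line had received either a control RNA or miRNA purified from epididymosomes (vesicles of the cauda epididymis) by injection; the control embryos carry no injection label.

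The deposited small RNA tables hold whole-number counts of reads for 2343 features, namely 1123 miRNAs, 467 piRNA loci, 435 tRNAs, 313 repeat families and 5 rRNAs, for 40 sperm and 42 tissue libraries. A further table deposited by the authors gives reads per RNA class and library as counts, with an expected count for mRNA. The mRNA and embryo tables hold TPM that the authors had computed and deposited for 23845 genes, and the columns of each table sum to nearly the same total, so sequencing depth is unknown for these 30 tissue and 313 embryo libraries. Bowtie2 and RSEM are named in the submitters' processing notes, and the genome build mm10 is named in the labels; versions are not given in the sources used here. Coordinates come from the RefSeq gene table for GRCm38, the same assembly as mm10, and are 1-based.

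The total count per small RNA library ranged from 6.16e5 to 3.87e7 reads, with a median of 8.88e6. For 74 of the 82 small RNA libraries the feature table and the class table gave equal miRNA, piRNA, rRNA and tRNA totals within 1%. In the 8 libraries of the second series of Defb41 cauda sperm the feature table held 1.03 to 2.08 times the miRNA reads of the class table, 1.49 to 5.31 times the piRNA reads, 1.01 to 1.51 times the tRNA reads and 10.9 to 37.3 times the repeat reads. Repeat totals differed in the other 74 too (0.135 to 1.50 times), so values of repeat families are uncertain. One small RNA library with conflicting title and genotype labels entered no comparison, and 1 column of the deposited tables that matched no sample was not used here. Nothing in the sources used here says that libraries of a group came from separate animals, so p-values measure the spread between libraries, which may be technical.

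Small RNA counts were compared with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood test with the total of the table as library size and no composition factor, on features with at least 10 counts in as many libraries as the smaller group. TPM values were compared with limma 3.58.1 (trend and robust options) on log2(TPM + 1), on genes with TPM of at least 1 in as many libraries as the smaller group, or in 0.25 of the embryos compared. The design fixed beforehand allowed for either unit and named this test for TPM. Fold changes of TPM are therefore on the log2(TPM + 1) scale, which understates the change of low genes. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and unless another tool is named each adjusted p of a gene comes from these tests. Errors given after ± are SDs between libraries or embryos; errors of log2 fold changes are SEs. Small RNA levels are in RPM, reads per 1000000 of the table total. Fits for Defb41 cauda sperm and for Stra8 caput and cauda small RNA held a term for the library series that the labels number; in tests that set Defb41 cauda against testis sperm, series 2 of cauda sperm was left out. Class shares were compared by two-sided exact permutation tests over libraries, adjusted over 60 tests.

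Gene lists fixed before the data were examined were tested with camera (a competitive test against all other genes) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The PValue of fry tests whether the genes of a set move, on balance, one way and does not compare the set with other genes. Adjusted p for lists are over the lists of a comparison. The 11 small RNA lists were the X-linked testis cluster, miR-34/449, miR-17-92 and paralogs, miR-30, let-7 and miR-98, miR-200 (epithelial), miR-10 with miR-99, miR-100 and miR-125, the families of miR-26, miR-29 and miR-148, muscle miRNAs, blood miRNAs and miRNAs made without Dgcr8. The 19 tissue lists were miRNA pathway, pri-miRNA hosts, initial segment, caput secretory genes, cholesterol synthesis, steroid hormone signalling, let-7 targets, germ cells and sperm, smooth muscle, basal cells, clear cells, fibroblasts and matrix, endothelium, macrophages, T, B and NK cells, interferon and inflammatory response, blood, adipocytes and proliferation. The 17 embryo lists were 2-cell zygotic genes, maternal oocyte transcripts, pluripotency and inner cell mass, trophectoderm, primitive endoderm, RNA processing factors, chromatin regulators, miRNA pathway, cytosolic ribosomal proteins, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, glycolysis, p53 and DNA damage response, paternally expressed imprinted genes, Y-linked genes, cumulus cells and sperm transcripts. Of the 338 list tests, 68 passed at the preset correlation and 3 with an estimated one, namely miR-34/449 and the X-linked cluster in Stra8 cauda epididymis and the initial segment list in Defb41 caput.

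Genes are named by a rule fixed in the same way. It takes Dgcr8 wherever measured; the 10 largest changes each way among genes past the threshold with a mean of at least 100 RPM or 5 TPM; up to 4 passing members of each list by smallest p; for lists with none, the 2 members with the highest mean; and, where no gene passed, the 3 smallest p. The text gives a part of these genes, and some are not reported here. miRNA precursors are named as in the files, with the suffix of the file names left out, piRNA loci by chromosome and band, and paralogous precursors, tRNA copies and piRNA loci with like sequences share reads, so their values are uncertain.

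Where they applied, results were recomputed with another scaling (TMM for counts, centring on the median gene for TPM), DESeq2 1.42.0 for counts, a pseudocount of 0.1 for TPM, no filter on low values, the replicate number or embryo set as a block, each library or embryo set left out in turn, embryos with few detected genes left out, 1 series alone or no series term, and means per embryo set. No embryo fell under the limit on detected genes, so that fit equalled the reported one and checked nothing. Alternatives chosen after seeing the data were the library size from the class table, miRNAs alone scaled to the miRNA total, near-identical embryo pairs joined, class shares from the feature table or without single libraries, single libraries left out in Defb41 cauda sperm and Stra8 caput small RNA, and other settings for the relation between contrasts. Replicate numbers paired the libraries, with every pair's deviations correlated above 0.1, in Stra8 caput mRNA (0.24 to 0.553) and Stra8 cauda mRNA (0.423 to 0.555); the pairing there rests on shared numbers in the labels and this correlation. Embryo sets were paired in Defb41 morulae of control RNA against control (0.127 to 0.275), in Stra8 cauda sperm 4-cell embryos, whose sets are dates (0.694 to 0.967), and in Stra8 cauda sperm morulae (0.125 to 0.421). Sets of Stra8 testis sperm embryos are runs of positions in the sample sheet.

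On simulated data with up to 100 changed features per size past the filter, at the real means and spreads, the share recovered at a log2 change of 1 was 23.6% for Stra8 testis sperm, 6% for Defb41 cauda sperm, 25.3% for Stra8 caput mRNA, 68.8% for Stra8 cauda mRNA, 92% for Defb41 morulae of control RNA against control and 74% for Stra8 testis sperm morulae. At a log2 change of 2 the shares were 72.9%, 66.7%, 80.2%, 94.8%, 99% and 97.9%, in the same order. Tests of position and class share used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.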

Results

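Small RNA, epididymal mRNA and embryo mRNA were measured in a pair of mouse lines. By design, Dgcr8 was deleted either in germ cells (Stra8 line) or in the epididymis (Defb41 line). Testis sperm (taken before the epididymis) and cauda sperm (taken from its end) gave 40 small RNA libraries, 4 per group except 8 control and 8 cKO libraries of Defb41 cauda sperm. The epididymis itself, as caput (head) and cauda (tail), gave 42 small RNA libraries, of which 41 entered groups of 3 to 8, and 30 mRNA libraries in groups of 3 or 4. Single embryos at the 4-cell and morula stages, 313 in all, came from testis sperm or cauda sperm of Stra8 males and from cauda sperm of Defb41 males, in groups of 15 to 30. Median depth per small RNA group lay between 5.56e6 reads in Stra8 testis sperm controls and 1.31e7 in Defb41 caput controls. One of the 3 libraries of the latter held 6.16e5 reads, so that group allows few firm statements.

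In testis sperm of the Stra8 line, the question was which small RNAs need Dgcr8 in germ cells. Mir184 fell from 7790 ± 1160 to 814 ± 453 RPM (n = 4 and 4; log2 change −3.26, SE 0.36, adjusted p = 0.000543), the largest called decrease among abundant miRNAs (GRCm38 chromosome 9, 89802260 to 89802328). Mir34c and Mir449a share a seed sequence and are abundant in male germ cells. They fell by 2.88 (SE 0.40, from 8480 ± 2290 to 1150 ± 633) and 3.16 (SE 0.37) on the log2 scale. Mir881 of the X-linked testis cluster (X, 66801944 to 66802021) fell from 2970 ± 1350 to 393 ± 166, and Mir470 of the same cluster from 3850 ± 755 to 834 (adjusted p = 0.00101 and 0.000543). Mir375, Mir192 and Mir25 fell by 3.03 (SE 0.41), 2.68 (SE 0.34) and 2.55 (SE 0.44). In all, 77 of 261 measured miRNAs fell and 0 rose, with 132 at an unadjusted p under 0.05. Of 372 tRNAs 70 fell and 2 rose (median log2 change −1.15), and of 460 piRNA loci 3 rose and 2 fell. As a class, miRNAs made up 7.39% ± 4.20 of reads in cKO against 19.1% ± 3.50 in control libraries (two-sided exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.0984). The rRNA fragments of 28S rose from 79100 ± 13700 to 139000 ± 38200 (log2 change 0.82, SE 0.22, adjusted p = 0.029), a call kept in 2 of 8 fits without 1 library (0.64 to 0.95), those without cKO replicate 1 or 2. Mir471, another member of the X-linked cluster, was counted at 21.8 ± 6.3 in controls and at 0 in all 4 cKO libraries.

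By list, 12 of 16 members of the X-linked cluster fell (15 when adjusted over the list alone), among them Mir465b-1 from 403 ± 48.6 to 63.1 ± 26.6, with a camera adjusted p = 1.1e-10 against adjusted p = 0.0671 with an estimated correlation. The miR-34/449 family had 3 of 5 lower (4 adjusted over the list alone; camera 0.0045, adjusted p = 0.054 with an estimated correlation), including Mir34b (591 ± 92.9 to 88.8 ± 47.7). The miR-17-92 clusters had 5 of 8 lower (6 adjusted over the list alone; 0.00953, adjusted p = 0.465 with an estimated correlation), such as Mir93 and Mir106b (128 ± 50 to 27.4 ± 13.3). The miR-30 family had 5 of 6 lower (6 adjusted over the list alone; 0.0045, adjusted p = 0.448 with an estimated correlation), Mir30a falling from 4140 ± 915 to 1190 ± 720. Of miR-200, 1 of 5 fell (4 adjusted over the list alone), namely Mir429. Of miR-10 with miR-99, miR-100 and miR-125, Mir100 alone of 8 fell (2 adjusted over the list alone). Of miR-26, miR-29 and miR-148, 2 of 8 fell (2), Mir148a going from 2150 ± 379 to 934 ± 299. Of let-7, Mirlet7g alone of 12 fell (1). None of 5 muscle, 6 blood or 6 Dgcr8-independent miRNAs passed, the last with a median log2 change of −0.68. Camera called none of these 7 lists. The all-feature median was −0.60, or −0.21 with TMM, and the 161 calls (8 higher, 153 lower) became 190 (55 higher, 135 lower). DESeq2 called 260, and leaving out cKO replicate 3 gave 94. Mir100, Mir429, Mirlet7g and Mir148a were called in 1, 2, 4 and 7 of 8 fits without 1 library, and 20 of 31 named features in all 8. With miRNAs scaled to the miRNA total 23 passed (10 higher, 13 lower), including Mir184 (−1.84), Mir449a (−1.72), Mir34c (−1.48) and Mir881 (−1.38). There Mir100 turned to 0.17 and Mir148a to 0.29.

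**Figure D1:**
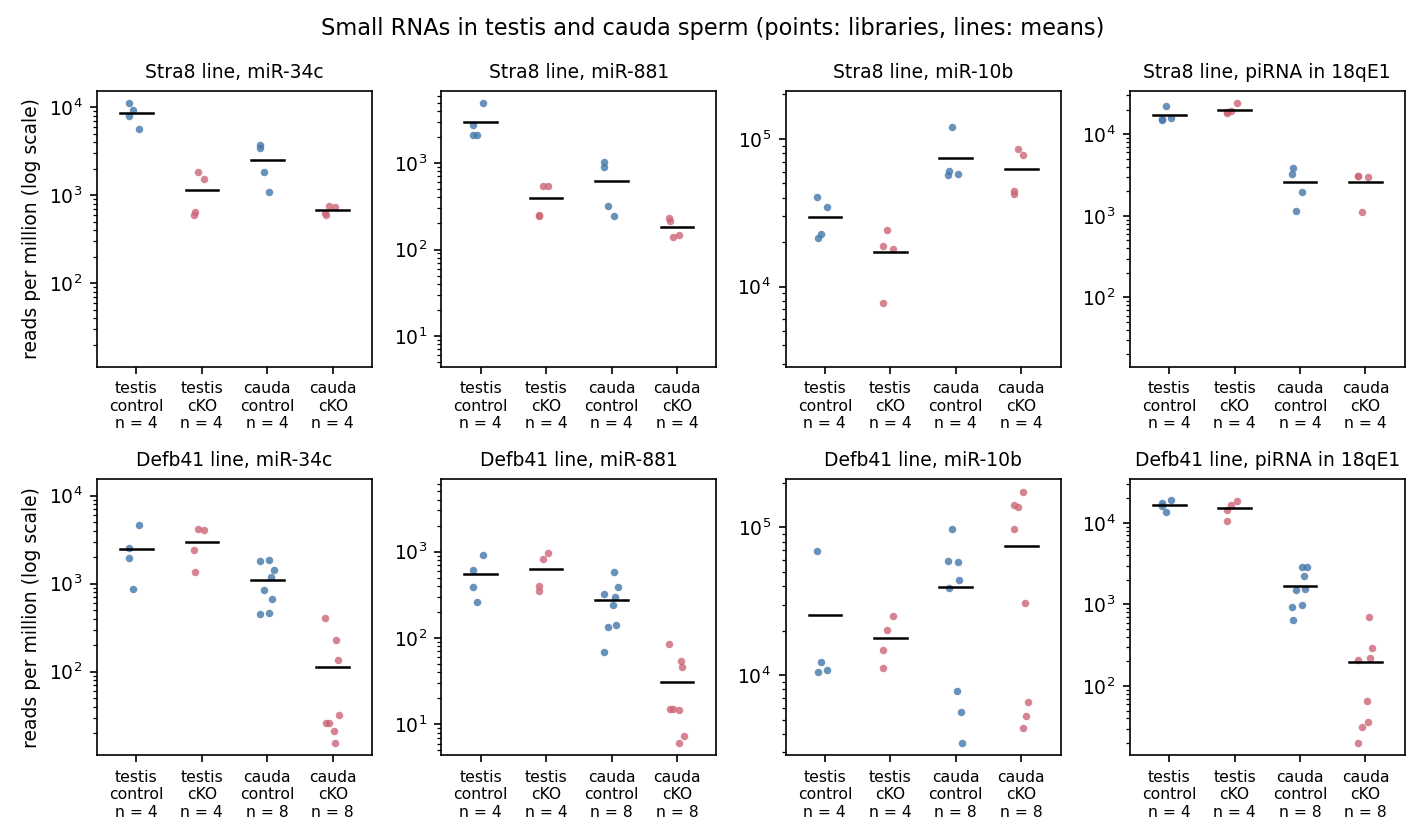
RPM (log axis) of 3 miRNAs and the piRNA locus in band qE1 of chromosome 18 in each sperm library of both lines, with lines at group means. Mir34c was lower in cKO testis sperm of the Stra8 line (means 8480 and 1150) and in cKO cauda sperm of the Defb41 line (1080 and 112).

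Cauda sperm of the Stra8 line showed a smaller set of lower miRNAs together with higher piRNA loci. Mir34c fell from 2510 ± 1250 to 678 ± 79.9 RPM (log2 change −1.89, SE 0.42, adjusted p = 0.0234, n = 4 and 4). Mir34b fell by 2.38 (SE 0.56), Mir375 by 2.05 (SE 0.52) and Mir871 of the X-linked cluster from 850 ± 299 to 215 ± 56.5. A piRNA locus in band qA3.3 of chromosome 17 rose from 76 ± 27.2 to 591 ± 221 (log2 change 2.96, SE 0.48, adjusted p = 0.00439) and one in band qA5 of chromosome 13 from 132 ± 46.9 to 879 ± 323. All 15 called piRNA loci were higher. Of the lists, 10 of 16 X-linked members fell (14 adjusted over the list alone; camera 5.49e-10, adjusted p = 0.489 with an estimated correlation). Lower too were 3 of 4 of miR-34/449 (3; 0.025, adjusted p = 0.489 with an estimated correlation) and 3 of 8 of miR-17-92 (7; 1.61e-04, adjusted p = 0.567 with an estimated correlation), including Mir19a, Mir20a and Mir93 (189 ± 94.2 to 62.5 ± 6.69). No member of the other 8 lists passed. rRNA made up 16.1% ± 5.17 of reads against 7.54% ± 2.23, and tRNA 62.8% ± 3.16 against 68.5% ± 2.00 (each two-sided exact permutation p = 0.0286, adjusted p = 0.0984). The 61 calls (23 higher, 38 lower; with TMM 46 and 45, the all-feature median moving from −0.19 to −0.03) were 149 with DESeq2 and 1 of 266 miRNAs when scaled to the miRNA total. Leaving out control replicates 1 to 4 gave 127, 134, 36 and 16 calls, and leaving out cKO replicates 1, 3 and 4 gave 13, 14 and 35. Of the 26 named features 10, all piRNA loci, stayed called throughout, and the miRNAs lost the call in at least 1 of these fits.

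The genotype effect differed between cauda and testis sperm of this line for 37 features (32 higher and 5 lower in cauda relative to testis; 19 and 11 with TMM, the median moving from 0.54 to −0.18). Among piRNAs, the same locus in band qA3.3 of chromosome 17 had the largest such difference (log2 3.35, SE 0.54, adjusted p = 0.00108). The locus in band qA5 of chromosome 13 followed at 2.99 (SE 0.50) and pi-Phf20.1 at 2.77. In the other direction the tRNA chrX.trna643-LysCTT differed by −4.40 (SE 1.08, adjusted p = 0.027), a call kept in 8 of 16 fits without 1 library (−4.80 to −3.54), where the other 11 named features stayed called in all. It had risen from 99.3 ± 57.5 to 1230 ± 1150 RPM in cKO testis sperm (3.64, uncalled at 3.37 without control replicate 2). No list passed camera in this test, and 57 features passed with DESeq2.

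Between testis and cauda sperm of controls, the small RNA pool changed from rRNA and piRNA to tRNA fragments in both lines. In Stra8 controls tRNA went from 5.03% to 68.5% of reads, piRNA from 40.9% to 5.83% and rRNA from 33.2% to 7.54%. In Defb41 controls (n = 4 and 4, cauda sperm of series 1) the same shares went from 1.12% to 71.2%, 43.5% to 3.52% and 41.0% to 8.57%. The glycine tRNA chr1.trna1400-GlyGCC rose from 943 ± 159 to 25700 ± 4670 RPM in Stra8 controls (log2 change 4.77, SE 0.36, adjusted p = 1.24e-09). In Defb41 controls chr13.trna77-GlyGCC rose from 216 ± 70.1 to 41200 ± 10400 (7.57, SE 0.69, adjusted p = 1.71e-18). Mir10a, encoded in a Hox cluster, rose from 3670 ± 1340 to 38300 ± 17500 and from 1840 ± 1590 to 37400 ± 13800. Mir141 of the epithelial miR-200 family rose from 327 ± 166 to 2510 ± 1890 and from 20.5 ± 11.3 to 2470 ± 1170. The miR-200 list had 4 of 5 higher in Stra8 (camera 0.0337, adjusted p = 0.773 with an estimated correlation) and 5 of 5 in Defb41 controls (0.00125, adjusted p = 0.824 with an estimated correlation), each count the same when adjusted over the list alone. Red cell miRNAs went down: Mir486 from 22900 ± 11600 to 387 ± 156 and from 12100 ± 4010 to 597 ± 461. Mir144 fell by 5.59 and 4.68 on the log2 scale. In all 5 of 6 and 4 of 6 blood miRNAs were lower (5 and 4 adjusted over the list alone), in lists that camera did not call. An abundant piRNA locus, also in band qA3.3 of chromosome 17, fell from 7830 ± 2630 to 668 ± 313 and from 11100 ± 2610 to 319 ± 215. In Stra8 controls 856 features passed (226 higher, 630 lower; with TMM 440 and 382, the median moving from −1.68 to 0.24). All 4 muscle miRNAs fell and none with TMM, among them Mir143 from 19700 ± 8060 to 5500 ± 1220, which turned to 0.20 with TMM. In Defb41 controls 812 passed (308 higher, 504 lower; with TMM 439 and 405, the median moving from −0.96 to 0.02).

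**Figure D2:**
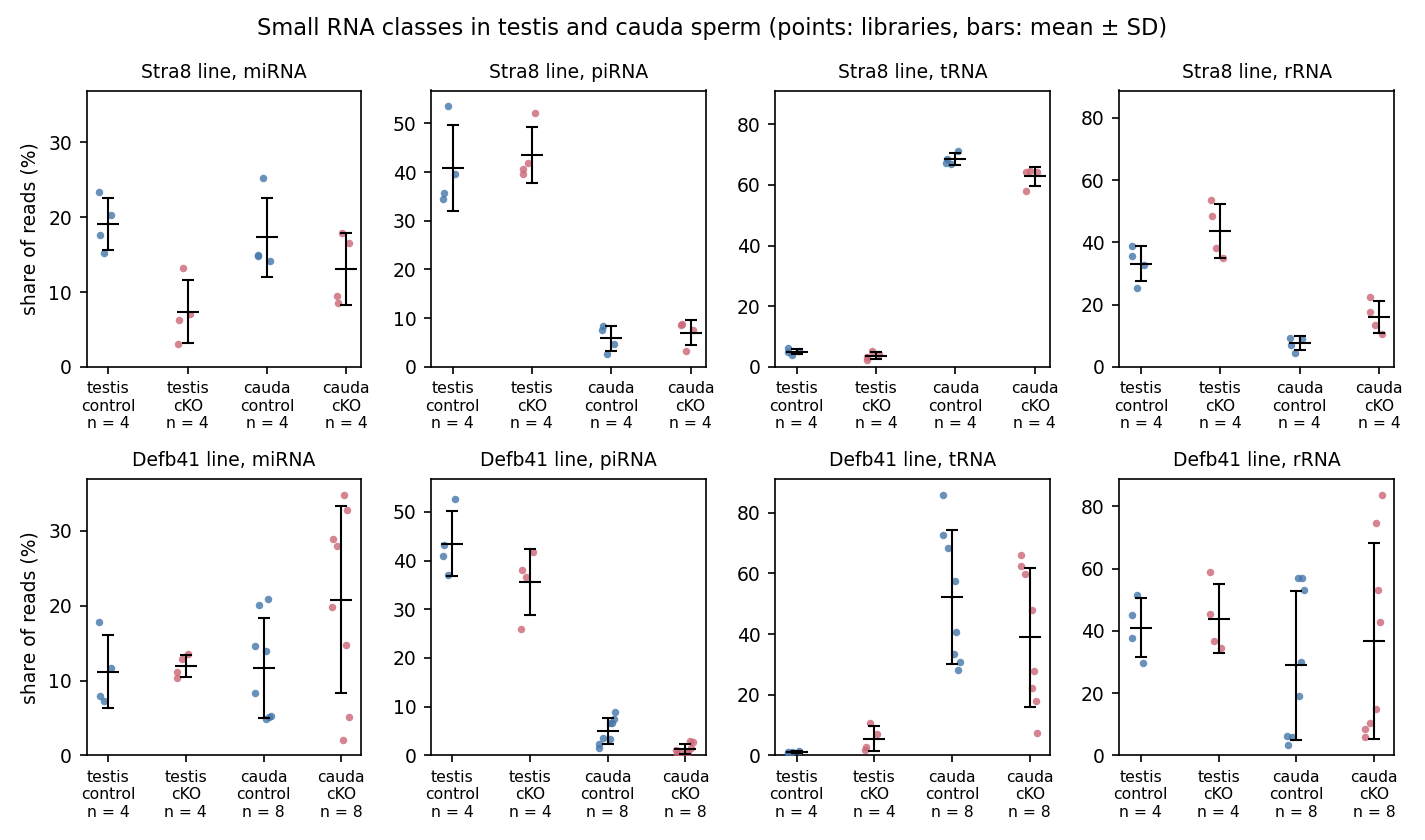
Share of reads (%) per small RNA class in each testis and cauda sperm library of both lines, with bars at the mean ± SD. Transfer RNA fragments make up most reads of cauda sperm in Stra8 controls (68.5%) and in series 1 of Defb41 controls (71.2%). They make up few in testis sperm of these controls (5.03% and 1.12%). Over both series of Defb41 cauda sperm the mean share was 52.2% in control libraries (28.1 to 85.9) and 38.9% in cKO libraries (7.33 to 66.0).

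In the epididymis of Stra8 males, whose own cells keep Dgcr8 by design, few small RNAs passed. In cauda, Mir34c fell from 181 ± 49.9 to 89.0 ± 40.1 RPM (log2 change −1.28, SE 0.17, adjusted p = 0.000858, n = 6 and 8). Mir34b fell from 11.5 ± 3.64 to 4.89 ± 2.81 and Mir881 from 161 ± 49.2 to 91.2 ± 28.9 (log2 change −0.67, SE 0.16, adjusted p = 0.0253). The miR-34/449 family had 3 of 4 lower (3 adjusted over the list alone; camera 1.24e-11, adjusted p = 0.0027 with an estimated correlation). The X-linked cluster had 3 of 13 lower (10; 3.93e-17, adjusted p = 0.00769 with an estimated correlation), though Mir465b-1, Mir465c-2 and Mir881, the 3 called, did not pass with TMM. Camera also placed miR-17-92 (0.00756, adjusted p = 0.497 with an estimated correlation) and miR-10 with miR-99, miR-100 and miR-125 (0.00103, adjusted p = 0.503 with an estimated correlation) lower, with 0 members past the threshold in each. The 20 calls were 9 lower miRNAs and 11 higher piRNA loci (with TMM 5 and 12), and 19 miRNAs fell when scaled to the miRNA total. Series 1 alone gave 0 calls and series 2 alone 1, no series term 7, and leaving out control replicate 4 gave 37. Mir34c, Mir34b and Mir449a stayed called without any single library, and Mir465b-1, Mir881 and Mir465c-2 in 7, 8 and 13 of 14 such fits. In caput, 0 of 1064 features passed with edgeR (103 at an unadjusted p under 0.05) and 0 with DESeq2 (n = 7 and 7), the all-feature median being −0.45, or −0.08 with TMM. There rRNA made up 41.8% ± 10.6 of reads in cKO against 28.8% ± 6.11 in control libraries, and miRNA 47.8% ± 11.4 against 58.4% ± 7.62 (two-sided exact permutation p = 0.00653 and 0.0171, both adjusted p = 0.0984).

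Testis sperm of the Defb41 line, in which germ cells keep Dgcr8 by design, served as the comparison for cauda sperm. None of 932 miRNAs passed edgeR (41 at an unadjusted p under 0.05), and no member of the 11 lists. Mir34c and Mir881, low in Stra8 cKO testis sperm, were not called. All 31 called features were tRNAs, such as chr13.trna77-GlyGCC, which rose from 216 ± 70.1 to 1130 ± 555 RPM (log2 change 2.38, SE 0.39, adjusted p = 0.0108, n = 4 and 4). Another was chr1.trna710-ValCAC, which rose from 515 ± 127 to 4790 ± 4820 (3.22, SE 0.68, adjusted p = 0.036). tRNA made up 5.48% ± 4.08 of reads in cKO and 1.12% ± 0.354 in control libraries (two-sided exact permutation p = 0.0286, adjusted p = 0.0984). With TMM 0 features passed (409 at an unadjusted p under 0.05; median from 0.40 to 0.18) and with DESeq2 101 (100 higher). Leaving out control replicates 1 to 4 gave 57, 11, 12 and 11 calls, and cKO replicates 1 to 4 gave 11, 18, 65 and 86. The tRNA chr13.trna77-GlyGCC stayed called in each, but chr1.trna710-ValCAC only without control replicate 1 or cKO replicate 3 or 4 (2.38 without cKO replicate 2 to 3.57 without cKO replicate 4), and 3 of 10 named features in all 8 fits.

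Cauda sperm of the Defb41 line carried lower levels of miRNAs and piRNAs typical of germ cells. Mir34c fell from 1080 ± 568 to 112 ± 143 RPM (log2 change −3.26, SE 0.56, adjusted p = 4.25e-06, n = 8 and 8). Mir881 fell from 274 ± 167 to 30.6 ± 28.7 (−3.16, SE 0.54), Mir449a from 117 ± 63.4 to 16.8 ± 14.9 and Mir743b from 100 ± 63.6 to 10.4 ± 8.87. A piRNA locus in band qE1 of chromosome 18 fell from 1700 ± 879 to 195 ± 226 (−3.46, SE 0.56, adjusted p = 3.99e-06) and one in band qC5 of chromosome 8 from 386 ± 209 to 41.7 ± 50.5. Reads of piRNA made up 1.27% ± 0.992 against 5.08% ± 2.69 (two-sided exact permutation p = 0.000408, the smallest this design allows, adjusted p = 0.0245), the only class share to pass of 60. That rests partly on group size, since 4 and 4 libraries allow no exact permutation p under 0.0286. Even the tRNA share of Stra8 controls, 5.03% in testis and 68.5% in cauda sperm, did not pass (exact permutation test, adjusted p = 0.0984). Mir21a, abundant in many somatic tissues, was called higher (848 ± 430 and 8570 ± 20300; 2.64, SE 0.61, adjusted p = 0.000487), as were Mir222 (2.25) and Mir221 (1.62), a pair with a shared seed. These 3 calls rest on cKO replicate 5: without it the log2 differences were 0.58, 0.51 and 0.38, none called. Mir34c, Mir881, Mir449a, Mir743b and both piRNA loci above stayed called without any single library. The X-linked cluster had 13 of 18 lower (15 adjusted over the list alone; camera 6.19e-13, adjusted p = 0.42 with an estimated correlation). The miR-34/449 family had 3 of 6 lower (3; 0.0397, adjusted p = 0.602 with an estimated correlation). Camera placed let-7 higher (0.00374), as it did the Dgcr8-independent miRNAs and the families of miR-26, miR-29 and miR-148 (0.0397 each). In these lists 0 members passed, and the adjusted p = 0.742 with an estimated correlation in each. In all 267 features passed (8 higher, 259 lower; with TMM 79 and 289, the median moving from 0.08 to 0.26), of which 180 were lower piRNA loci, 53 lower tRNAs and 25 lower miRNAs. Without a series term there were 96, and in series 2 alone 14 (5 higher, 9 lower), against 248 in series 1.

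The difference between the genotype effects in cauda and testis sperm of this line, tested without series 2, passed for 314 features (2 higher, 312 lower; the median was −0.53, or −0.37 with TMM). Mir449a differed by −3.74 (SE 0.97, adjusted p = 0.00806), Mir34c by −3.63 (SE 1.07, adjusted p = 0.0187), Mir881 by −3.31 (SE 0.93; −2.65 and uncalled without cauda sperm control replicate 1) and the piRNA locus in band qE1 of chromosome 18 by −4.19 (SE 0.87). Without 1 library, Mir449a ranged from −5.71 to −3.41, Mir34c from −6.03 to −3.26 and that piRNA locus from −5.52 to −3.65, each called in all 16 fits. Of the X-linked cluster 7 of 19 were lower (12 adjusted over the list alone; camera 0.000452, adjusted p = 0.749 with an estimated correlation). Scaled to the miRNA total, 8 miRNAs passed in place of 19.

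In the epididymis of Defb41 males few miRNAs passed. Segment was checked in mRNA only, where labels of this line are in doubt, so these small RNA groups are as labelled. Defb41, the gene that the Cre is named for, stood at 162 to 236 TPM in Stra8 control caput mRNA. It stood at 0 to 0.89 in Stra8 control cauda mRNA, and whether Dgcr8 was deleted in the cauda was not checked. In cauda, Mir871 went from 95.4 ± 17.5 to 19.9 ± 3.48 RPM (log2 change −2.26, SE 0.43, adjusted p = 0.0463, n = 4 and 3). Mir465c-1 went from 68.9 ± 36.0 to 12.7 ± 6.34, both X-linked, along with Mir743b and Mir878. The X-linked cluster had 5 of 14 lower (11 adjusted over the list alone; camera 3.24e-06, adjusted p = 0.33 with an estimated correlation), and 60 piRNA loci fell. None of 12 let-7 or 8 members of the list of miR-10 with miR-99, miR-100 and miR-125 passed. The 71 calls (2 higher, 69 lower) became 1 with TMM (median from −0.53 to 0.06), 147 with DESeq2, and 0 with miRNAs scaled to the miRNA total (49 at an unadjusted p under 0.05). Without control replicate 1 there were 163 calls. Leaving out any other single library gave 0. In caput 0 of 1406 features passed with edgeR (63 at an unadjusted p under 0.05; n = 3 and 3; median −0.19, or −0.07 with TMM), 10 with DESeq2 and 1 without control replicate 2, the library with 6.16e5 reads. Camera placed let-7 higher (0.0182, adjusted p = 0.627 with an estimated correlation). Caput control libraries were uneven, with piRNA at 0.264% to 35.6% of reads and miRNA at 44.7% to 86.6%.

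Dgcr8 mRNA (GRCm38 chromosome 16, 18253948 to 18289251) was low in all epididymal libraries. In Stra8 males it was 1.44 ± 0.587 TPM in control and 1.48 ± 0.837 in cKO caput (n = 3 and 3; adjusted p = 0.998), and 2.22 ± 0.698 and 1.28 ± 0.494 in cauda (n = 4 and 4; adjusted p = 0.385). In Defb41 males it was 1.2 ± 0.337 TPM in the libraries labelled caput control and 2.41 ± 0.648 in those labelled caput cKO (log2 change 0.62, SE 0.19, adjusted p = 0.0196). Centred on the median gene the change was 0.42 (adjusted p = 0.0505; 0.0121 to 0.0641 over all alternatives). In the libraries labelled cauda control and cauda cKO it was 1.52 ± 1.09 and 2.90 ± 0.986 (adjusted p = 0.169; 0.0371 when centred, and 0.0371 to 0.39 over all alternatives). Levels are for the whole gene and the deleted exons are not given in the sources used here, so these values do not check the deletion. In the Defb41 line, the libraries labelled caput cKO stood with Stra8 control cauda by profile (r = 0.972 to 0.985). Those labelled cauda control stood nearer to caput, so these Dgcr8 differences hold segment as well as genotype.

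In the caput of Stra8 males, transcripts of late germ cells were higher in cKO than in control libraries. Prm2 rose from 328 ± 46.9 to 1390 ± 127 TPM (log2 change 2.09, SE 0.14, adjusted p = 0.000465, n = 3 and 3). Tnp2 rose from 76.7 ± 15.7 to 535 ± 186 and Tnp1 from 40.6 ± 9.13 to 300 ± 113, genes of the proteins that replace histones in spermatids. Hmgb4, Spata19 and Fabp9, also testis genes, rose by 3.28 (SE 0.39), 2.77 (SE 0.40) and 2.71 (SE 0.47). Rmrp and Rpph1, the RNA parts of RNase MRP and RNase P, fell from 100 ± 34.2 to 22.6 ± 2.44 and from 172 ± 41.6 to 41.9 ± 8.11. The germ cell list had 10 of 12 higher (12 adjusted over the list alone; camera 2.76e-22, adjusted p = 0.0887 with an estimated correlation). Camera placed blood genes lower (2.77e-07, adjusted p = 0.105 with an estimated correlation; Hbb-bs 295 ± 74.4 and 124 ± 71.1, not called). It also placed lower cholesterol synthesis (0.0232) and, against a list median of 0.095, the initial segment list (0.0337), both with adjusted p = 0.688 with an estimated correlation. Gpx5, an epididymal peroxidase of that list, was at 26000 ± 5850 and 30000 ± 3600. The 97 calls (95 higher, 2 lower, median 0.21, or 0.00 with 58 calls when centred) were 322 with the replicate number as a block. There camera, run with the block at the preset correlation only, also placed proliferation genes lower (adjusted p = 0.0276 against 0.0528). Calls numbered 185 and 193 without control replicates 1 and 2, and 14 and 1 without cKO replicates 2 and 3. Prm2 alone of the 15 named genes stayed called in each fit.

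Cauda of Stra8 males gave 0 calls with limma (1461 at an unadjusted p under 0.05, n = 4 and 4; median −0.15, or 0.00 when centred), and 295 (44 higher, 251 lower) with replicate number as a block. Crisp1, a secreted protein that coats sperm, was at 6470 ± 933 TPM in control and 3820 ± 348 in cKO libraries (log2 difference −0.75, SE 0.11, adjusted p = 0.295; 0.00772 with the block, over a range of alternatives from 0.00772 to 0.569). Prm1 and Prm2 were at 260 ± 158 and 1320 ± 833, and 853 ± 544 and 2790 ± 1250, neither called. The germ cell list had 0 of 12 past the threshold (8 adjusted over the list alone; camera 3.87e-17, adjusted p = 0.557 with an estimated correlation). Spag11b (26.7 ± 23.5 and 1.67 ± 1.08) and Cst11, of the caput secretory list, had the next smallest p-values, and that list had 7 of 44 lower when adjusted over the list alone. Without control replicate 3, and likewise without cKO replicate 3, 1 gene passed.

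Epididymal mRNA of the Defb41 line did not stand where its labels put it. All 4 libraries labelled caput cKO correlated more closely with Stra8 control cauda (r across genes 0.972 to 0.985) than with Stra8 control caput (0.658 to 0.692). All 4 labelled cauda control correlated more closely with caput (0.852 to 0.898) than with cauda (0.741 to 0.783). The other 8 libraries stood with their own segment. The values that follow are therefore of libraries labelled so. Lcn8, a lipocalin of the caput (GRCm38 chromosome 2, 25653118 to 25656217), was at 33200 ± 8330 TPM in libraries labelled caput control and 1.37 ± 0.637 in those labelled caput cKO (log2 change −13.79, SE 0.23, adjusted p = 1.15e-12, n = 4 and 4). Spag11b was at 23600 ± 5900 and 1.40 ± 0.831. The beta-defensin Defb28 was at 6.33 ± 1.11 and 16700 ± 2940 (11.15, SE 0.16). In the cauda labels, Crisp1 was at 1.33 ± 1.36 in control and 7960 ± 1960 in cKO libraries (11.85, SE 0.32, adjusted p = 1.22e-09). Gpx5 was at 19200 ± 11900 and 86.1 ± 57.0 and Lcn2 at 11500 ± 3070 and 442 ± 330. Mirlet7bhg, the host transcript of let-7b, was at 117 ± 37.4 in libraries labelled cauda control against 3.56 ± 0.857 in cauda cKO, 9.91 ± 6.45 in caput control and 3.25 ± 0.537 in caput cKO.

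**Figure D3:**
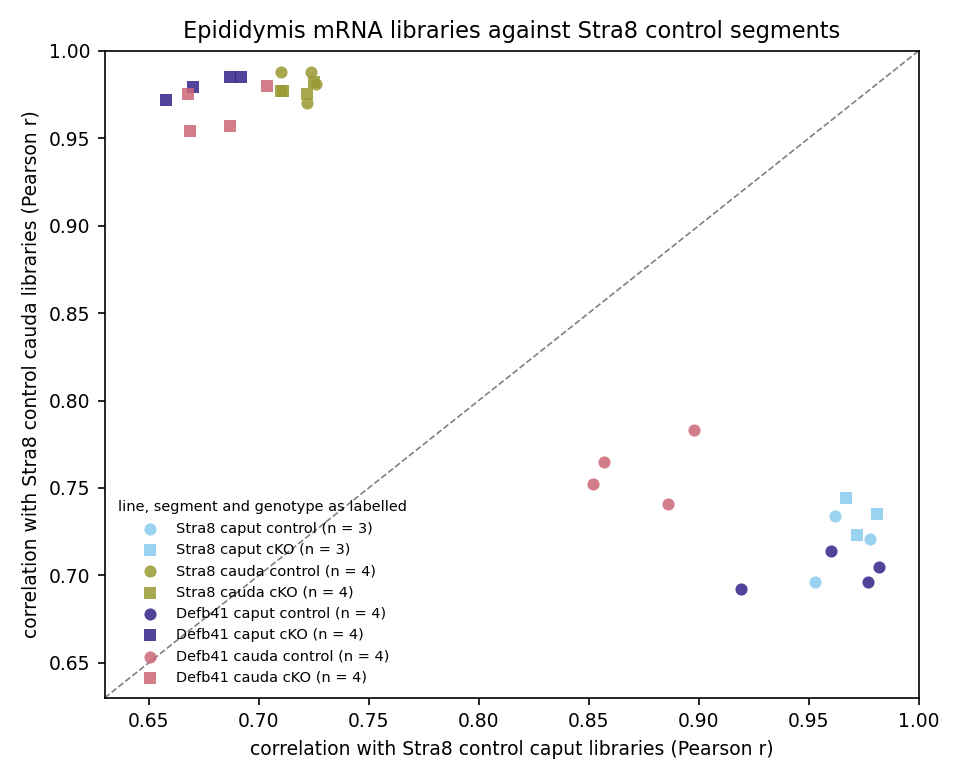
Pearson correlation across genes of each epididymal mRNA library with the Stra8 control caput (x axis) and Stra8 control cauda libraries (y axis); the dashed line marks equal values. Libraries labelled Defb41 caput cKO lie with cauda (0.972 to 0.985) and those labelled Defb41 cauda control lie on the caput side (0.852 to 0.898).

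By list, in the caput labels 14 of 15 initial segment genes were lower (14 adjusted over the list alone; camera 5.42e-15, adjusted p = 0.0129 with an estimated correlation). Caput secretory genes went both ways, 19 higher and 28 lower of 50 (19 and 28; camera lower, 1.18e-05). Smooth muscle genes rose, 9 of 10 with 1 lower (camera 2.59e-05), such as Tagln from 163 ± 26.3 to 1890 ± 204 and Des by 3.52. Germ cell genes rose, 12 of 12 (6.58e-05), such as Smcp by 2.90 and Prm2 by 2.58 (SE 0.16). Macrophage genes fell, 6 of 8 (7 adjusted over the list alone; 0.000554), such as Cd68 from 42.5 ± 5.73 to 7.08 ± 2.12. Endothelial genes fell, 4 of 5 (4; 0.00273), such as Tie1 by 2.34. For these 5 lists the adjusted p = 0.33 with an estimated correlation. Of lists that camera did not call, higher and lower genes numbered, in order, for the miRNA pathway 5 and 1 of 11 (Xpo5 among them), pri-miRNA hosts 3 and 1 of 4, and cholesterol synthesis 10 and 1 of 21 (10 and 2 adjusted over the list alone). For steroid hormone signalling they were 0 and 3 of 7, let-7 targets 4 and 0 of 5 (Ccnd2 rising by 2.88), basal cells 1 and 1 of 6 (1 and 0 adjusted over the list alone) and clear cells 4 and 0 of 6 (Atp6v1c2 from 4.28 ± 0.655 to 54.2 ± 5.91). For fibroblasts they were 2 and 1 of 10, interferon 1 and 1 of 8, blood 0 and 3 of 4, and proliferation 0 and 3 of 7 (2 adjusted over the list alone). The 2 measured genes of T, B and NK cells and the 2 of adipocytes did not pass. In the cauda labels, smooth muscle genes were higher in 10 of 10 (camera 2.61e-11, adjusted p = 0.273 with an estimated correlation), Actg2 rising by 2.39 (SE 0.26). Macrophage genes were lower in 7 of 8 (0.000552, adjusted p = 0.351 with an estimated correlation), Cd68 going from 128 ± 71.6 to 8.85 ± 2.89. Lower too were 7 of 12 initial segment genes (8 adjusted over the list alone; 0.00105, adjusted p = 0.318 with an estimated correlation). So were 6 of 9 interferon genes (7; 0.00315, adjusted p = 0.318 with an estimated correlation) and 8 of 9 proliferation genes (9; 0.00315, adjusted p = 0.455 with an estimated correlation), such as Cdk1 by 2.31. Totals were 6042 genes in caput labels (3900 higher, 2142 lower; centred 2851 and 3036, median from 0.24 to 0.04). There were 3099 in cauda labels (866 higher, 2233 lower; centred 1268 and 1522, median from −0.16 to 0.03).

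Embryos fathered with testis sperm of Stra8 males were compared at each stage. Dgcr8 in 4-cell embryos was at 17.4 ± 11.5 TPM in control and 16.4 ± 9.72 in cKO embryos (n = 22 and 22). At that stage the proteasome gene Psma4 fell from 463 ± 99.7 to 339 ± 51.3 (log2 change −0.44, SE 0.08, adjusted p = 0.0205). Junb, named here after its value was seen, was the other of 2 calls, both lower. Camera placed maternal transcripts higher (4.54e-07) and ribosomal proteins lower (7.56e-11), with 0 members past the threshold and adjusted p = 0.242 with an estimated correlation for both. In morulae (n = 27 and 21) the splicing factor gene Bud13 rose from 42.9 ± 19.3 to 70.2 ± 19.3 (0.77, SE 0.15, adjusted p = 0.0203). Wtap, part of the RNA methyltransferase complex, rose from 802 ± 303 to 1300 ± 569, and Pnldc1, a piRNA-trimming nuclease, from 5.18 ± 3.83 to 14.5 ± 8.84. Atp5k, an ATP synthase subunit, fell from 895 ± 200 to 660 ± 110 (−0.43, SE 0.08, adjusted p = 0.0203). Tmsb10 fell from 454 ± 204 to 274 ± 72.4, Rps9 from 2480 ± 316 to 2070 ± 257 and Tspan8 of the trophectoderm list from 5.40 ± 5.77 to 1.43 ± 2.15. Ribosomal proteins had 1 of 40 lower (5 adjusted over the list alone; camera 3.42e-18, adjusted p = 0.127 with an estimated correlation). Oxidative phosphorylation genes were placed lower (0.00063, adjusted p = 0.214 with an estimated correlation). Genes of 2-cell zygotic activation were placed higher (0 of 11 past the threshold, 3 adjusted over the list alone; 8.73e-05) and trophectoderm genes lower (1 of 16, 1; 1.83e-05), with adjusted p = 0.147 with an estimated correlation for both. The 22 calls in morulae (15 higher, 7 lower) were 11 when centred (5 and 6), 12 without a filter, 0 on means per embryo set (534 at an unadjusted p under 0.05), and 14, 60, 1 and 2 without sets 1 to 4. None of the 15 named genes stayed called in all 4 of these fits, and Rps9 was called in 0 of them. The 2 calls at the 4-cell stage were 0, 7, 1 and 1 without sets 1 to 4, 1 when centred and 0 on set means (549 at an unadjusted p under 0.05).

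Embryos fathered with cauda sperm of Stra8 males gave 0 calls with limma at both stages. At the 4-cell stage (n = 18 and 15; 281 genes at an unadjusted p under 0.05) Dgcr8 was at 15.4 ± 6.62 and 19.6 ± 9.93 TPM. The smallest p-values belonged to Donson, a replication factor (log2 difference −0.94, SE 0.23), Sesn3 and Slc48a1. Camera placed 2-cell zygotic (0.0322) and maternal transcripts (8.59e-06) lower, each with adjusted p = 0.65 with an estimated correlation. With the set as a block, where camera was run at the preset correlation only, it placed oxidative phosphorylation genes higher (adjusted p = 0.0188 against 0.287). In morulae (n = 20 and 22; 804 genes at an unadjusted p under 0.05) the smallest p-values belonged to 1110001J03Rik (0.72, SE 0.16, adjusted p = 0.335), Suox and Dio1. There 2-cell zygotic (0.00781) and maternal transcripts (0.00894) were placed higher, each with adjusted p = 0.496 with an estimated correlation. Trophectoderm genes were placed lower (4 of 16 adjusted over the list alone; 2.88e-05, adjusted p = 0.308 with an estimated correlation).

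For cauda sperm of Defb41 males, embryos of cKO fathers had received control RNA or epididymosome miRNA, and the question was whether the miRNA undid the difference from control embryos. Dgcr8 at the 4-cell stage was at 8.93 ± 8.68 TPM in control (n = 30), 11.4 ± 7.49 in cKO with control RNA (n = 23) and 9.53 ± 7.38 in cKO with miRNA (n = 21). At that stage 0 genes passed limma in each of the 3 contrasts (791, 742 and 404 at an unadjusted p under 0.05; centring moved the median from 0.16 to −0.01 and from −0.14 to 0.03 in the first pair). Hnrnpu, a nuclear RNA-binding protein, was at 79.4 ± 40.4 in control and 147 ± 92.5 in cKO with control RNA (0.78, SE 0.21, adjusted p = 0.56). Actr5 and Pex6 were among the genes with the smallest p between cKO with miRNA and cKO with control RNA (log2 differences −1.42 and −1.68). Against control, camera placed ribosomal proteins lower in both cKO groups (1.53e-07 and 5.7e-07, adjusted p = 0.331 and 0.577 with an estimated correlation). It did likewise with p53 genes (0.0164 and 0.0287, adjusted p = 0.331 and 0.577 with an estimated correlation).

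Morulae of cKO fathers with control RNA (n = 24) differed from control morulae (n = 26), which carry no injection label, in 15 genes. Srsf9 rose from 22 ± 5.55 to 43.1 ± 14.5 TPM (log2 change 0.91, SE 0.15, adjusted p = 0.000355) and Srsf2 from 74.9 ± 34.4 to 167 ± 69.3 (1.10, SE 0.20, adjusted p = 0.0012), both splicing factors. The RNA-binding protein gene Hnrnpab rose from 81.4 ± 16.3 to 124 ± 28.7 (0.58, SE 0.10). Odc1, the first enzyme of polyamine synthesis, rose from 247 ± 51.4 to 366 ± 86.7. The cell death regulators Mcl1 and Bbc3 rose by 0.67 (SE 0.13) and 0.97 (SE 0.22). Rab5a of early endosomes rose by 0.90 (SE 0.18) and Grsf1 from 15.7 to 40.5. Sdcbp fell from 43.6 ± 11.5 to 28 ± 11.2 and the spindle protein gene Tacc3 from 146 ± 26.2 to 109 ± 26.1. RNA processing had 2 of 30 higher (5 adjusted over the list alone; camera 0.00658, adjusted p = 0.331 with an estimated correlation) and p53 response 1 of 15 (1; 0.00658, adjusted p = 0.331 with an estimated correlation). With 0 members past the threshold, camera placed higher the 2-cell zygotic genes (5 of 11 adjusted over the list alone; 6.54e-05, adjusted p = 0.249 with an estimated correlation; Obox6 803 ± 311 and 1140 ± 531). Also placed higher were chromatin regulators (2 of 30; 0.00548, adjusted p = 0.292 with an estimated correlation), maternal transcripts (0.0171, adjusted p = 0.331 with an estimated correlation). The miRNA pathway was placed higher too (0.0369, adjusted p = 0.331 with an estimated correlation; 0.0985 with the set as a block) and ribosomal proteins (0.0369, adjusted p = 0.549 with an estimated correlation). Trophectoderm genes were placed lower (7 of 16 adjusted over the list alone; 6.54e-05, adjusted p = 0.249 with an estimated correlation), Krt8 standing at 587 ± 226 and 399 ± 283, uncalled. No member of the inner cell mass, primitive endoderm, oxidative phosphorylation, glycolysis, imprinted and Y-linked lists passed and camera called none of them. Cumulus cells and sperm transcripts had 1 measured gene each, uncalled, and mitochondrially encoded genes 0. These 15 calls (13 higher, 2 lower) were 24 when centred, 0 on means per set (281 at an unadjusted p under 0.05), and 8, 0 and 2 without sets 2, 3 and 4, so none of the 11 named genes stayed called in all of these fits.

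**Figure D4:**
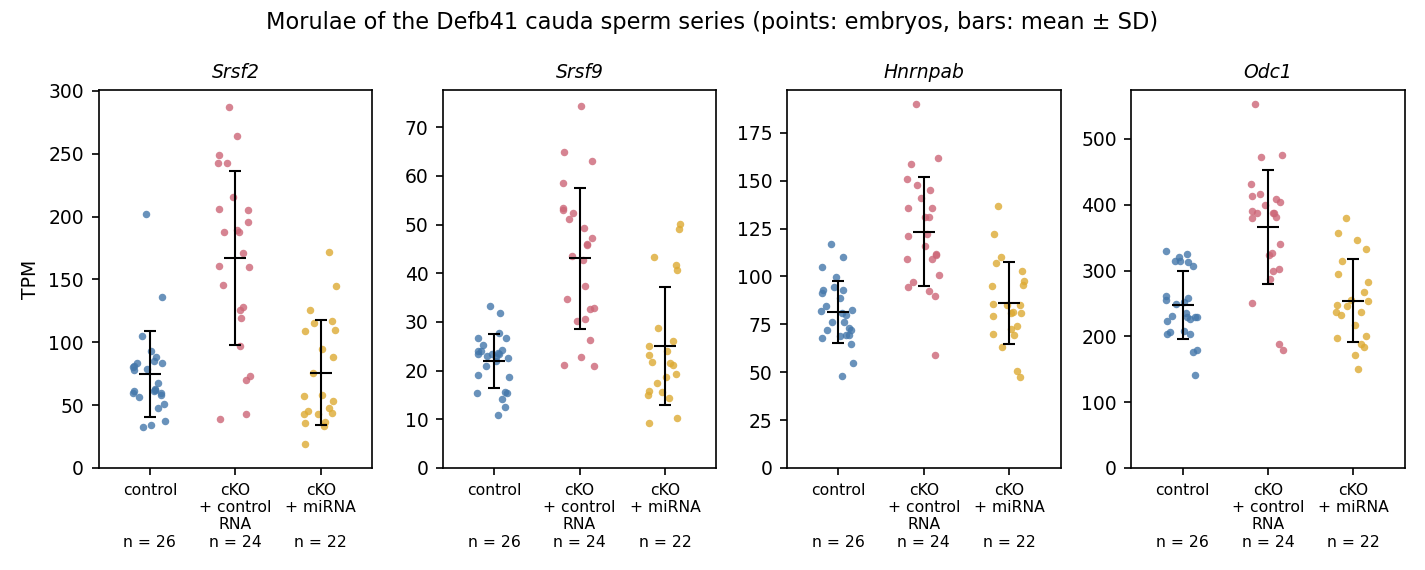
TPM of 4 genes in each Defb41 morula, by group, with bars at the mean ± SD. Mean Srsf2 was 74.9 in control, 167 in cKO with control RNA and 75.9 in cKO with miRNA.

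Morulae of cKO fathers with miRNA (n = 22) were lower in the same 4 genes than those with control RNA. Srsf2 fell from 167 ± 69.3 to 75.9 ± 41.8 TPM (log2 change −1.17, SE 0.21, adjusted p = 0.00258). Srsf9 fell from 43.1 ± 14.5 to 25.1 ± 12.2, Hnrnpab from 124 ± 28.7 to 86.0 ± 21.4 and Odc1 from 366 ± 86.7 to 254 ± 62.7 (adjusted p = 0.00456, 0.00658 and 0.00701). Ppp2ca, the catalytic subunit of a phosphatase, fell by 0.92 (SE 0.18), Dapk3 by 1.81 (SE 0.38), Yrdc by 1.56 (SE 0.33) and Pcbp1 by 0.41 (SE 0.09). RNA processing had 3 of 30 lower (6 adjusted over the list alone; camera 0.0122). Chromatin regulators (0.0253) and the miRNA pathway (0.0326) were placed lower and oxidative phosphorylation higher (0.0326), each with adjusted p = 0.422 with an estimated correlation. The 14 calls (1 higher, 13 lower) were 0 on means per set (665 at an unadjusted p under 0.05) and 4, 183, 0 and 0 without sets 1 to 4. When embryos were exchanged within sets, 7 of 100 splits called as many genes, so chance is not excluded for this contrast or its 4 genes. Between cKO with miRNA and control, 0 genes passed limma (1830 at an unadjusted p under 0.05; 6 with a pseudocount of 0.1, and 2 and 134 without sets 2 and 3). That count depended on how the sets were treated and does not show that the difference was undone. The smallest p there belonged to Fzr1, an activator of the anaphase-promoting complex, at 66.5 ± 20.7 and 37.5 ± 18.2 (−0.89, SE 0.18, adjusted p = 0.056). Camera again placed 2-cell zygotic genes higher (4 of 11 adjusted over the list alone; 1.18e-07, adjusted p = 0.0925 with an estimated correlation), trophectoderm genes lower (2 of 16; 0.00279) and Y-linked genes higher (0.0219), the last 2 with adjusted p = 0.426 with an estimated correlation.

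Both contrasts of the Defb41 embryos use the cKO embryos with control RNA, so opposite changes arise without any effect. Across 11073 genes in morulae the log2 changes of cKO with control RNA against control and of cKO with miRNA against cKO with control RNA had Pearson r = −0.44 (Spearman −0.42). There 1000 simulations without effects gave a mean of −0.49 (central range, with the extreme tails left out, −0.67 to −0.29). Genes are not independent replicates. The covariance was −0.0305, within the central range of the simulated covariance (mean −0.0208, −0.0366 to −0.0101). When the shared embryos were split between the contrasts, r was −0.13 (−0.32 to 0.14 over the draws). At the 4-cell stage r was −0.59 (Spearman −0.59, simulated −0.52, central range −0.64 to −0.38). The covariance was −0.0695 against −0.0515 (central range −0.0787 to −0.0355), and r with split embryos −0.14 (−0.24 to −0.03 over the draws). Of the 15 and 14 genes called in morulae, 4 were shared in opposite directions and 0 in the same direction. Independent lists would share 0.0153, but these contrasts are not independent, as the shared embryos enter them with opposite sign. Of refits without effects, 1 of 100 had a shared opposite call. Neither number separates an effect of the miRNA from a difference that lies in the shared embryos alone. The shared genes were Srsf2, Srsf9, Hnrnpab and Odc1.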

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

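The tests of exchanged labels, of segment identity, of mixed tissue in the libraries labelled cauda control, and all tests on the germline RNA of Defb41 cauda sperm were chosen only after the results they concern had been seen.

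Among epididymal mRNA libraries of the Defb41 line, those labelled caput cKO held cauda transcripts, and those labelled cauda control stood on the caput side but held little of some caput genes. Crisp1 stood at 7260 to 11800 TPM in the libraries labelled caput cKO and at 0.58 to 3.36 in those labelled cauda control, and Gpx5 at 72.6 to 171 and 7260 to 35700, while Lcn8 (22.2 to 572), Lcn9 (0.97 to 356) and Cst8 (4.6 to 196) in the latter were far below caput control (25200 to 42300, 7840 to 11100 and 3610 to 5700). If the labels are right, a change of segment identity in cKO males alone does not account for the 4 of 4 libraries labelled cauda control that also stood nearer to caput. If labels were exchanged, this count cannot decide, since those libraries would be of cKO males. It is also part of the observation itself. Mixed caput and cauda tissue is argued against in the libraries labelled caput cKO, whose lowest position on the axis from caput (0) to cauda (1) was 1.01, and in those labelled cauda control, where 41 of 44 cauda genes were under 0.25 of their lowest control level, which leaves room for little cauda tissue, yet 15 of 83 caput genes were too. Labels exchanged between these groups cannot be told apart from other causes, since the 8 of 8 libraries with the other segment and 0 of the other 8 are the observation itself. Under exchanged labels, the low Lcn8 and the Mirlet7bhg level (94.9 to 173 TPM against 4.34 to 19.2 in caput control) would be differences of caput cKO from caput control. Their cause was not tested.

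In Defb41 cauda sperm, germline miRNAs and piRNAs were lower in cKO, although by design Dgcr8 was deleted in the epididymis, which the mRNA values do not check. The summed X-linked cluster changed by −2.54 (SE 0.47) in cauda sperm and by 0.20 (SE 0.30) in testis sperm, which argues against a loss of miRNA processing in germ cells. A difference between library series is argued against by a change of −3.17 (SE 0.65) in series 2 beside −1.91 (SE 0.68) in series 1. A lower share of sperm RNA in the cKO libraries could lower both kinds of RNA alike and cannot be told apart from other causes: the change of the X-linked cluster minus that of piRNAs was −0.97 (SE 0.36) with piRNAs of the feature table, which counted against it, and −0.38 (SE 0.31) with those of the class table. The class table was brought in only after the first value had been seen, and the test then asked for both. The reason was that feature-table piRNAs of series 2 were 1.49 to 5.31 times those of the class table. Series 1 gave 0.41 with the feature table (SE 0.36) and with the class table (SE 0.37). Series 2 gave −2.35 (SE 0.61) and −1.17 (SE 0.5) in that order. In both versions the X-linked cluster was a share of the feature table, while class-table piRNAs were a share of the class table. The second value thus mixes different totals in series 2, where the tables disagree, and is no independent check. Series 2 alone counted against a lower share with piRNAs of either table, and series 1 did not.

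In morulae, 2-cell zygotic genes stood higher and trophectoderm genes lower in 4 comparisons of cKO with control embryos, with camera calls that were lost with an estimated correlation. The score of the first list minus the second was higher within sets in 4 of 4 comparisons (permutation p = 0.00123, 0.00013, 3e-05 and 0.0261). That argues against a difference between embryo sets in Defb41 morulae of control RNA against control and in Stra8 cauda sperm morulae, whose sets were paired. It cannot decide for miRNA against control (pair correlations 0.021 to 0.261) and Stra8 testis sperm (0.03 to 0.634). There not every pair correlated above 0.1, so equal set numbers may not mark shared sets. Less advanced morulae in the cKO groups may underlie the higher score. Over genes outside both lists, the position between 4-cell and morula differed by −0.103 and −0.107 in the Defb41 line, −0.0667 in Stra8 testis sperm and −0.0661 in Stra8 cauda sperm. The permutation p was under 0.05 in 3 of 4 comparisons (0.00293, 0.00222, 0.162 and 0.0174) and within sets in all (0.00362, 7e-05, 0.018 and 0.0162). These permutations exchanged single embryos, and the labels do not name the fathers, so their p-values do not cover differences between fathers. The Defb41 comparisons share their control embryos, and the time of collection and the genotype of the father stay open, as does the injection in the Defb41 line.

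The effect of the genotype differed between cauda and testis sperm for 37 features in the Stra8 line and 314 in the Defb41 line, by a test of the difference itself.

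Of 311 sets of values, each of 1 feature, class share or depth in 1 group of 4 to 10 libraries, 30 held a library far from the others, 9.65%. Chance gives about 1 in 20, but sets that share libraries are not independent, so these shares cannot be compared as a test. In Defb41 cauda sperm, cKO replicate 5 held Mir21a at 58800 RPM (others 173 to 2530), Mir222 at 3890 (16.3 to 138) and Mir221 at 1710 (22.6 to 205), so the mean of each rests largely on that library, and none was called without it (log2 0.58, 0.51 and 0.38). Replicate 8 of the controls there held Mir486 at 5450 (87.3 to 1530), Mir144 at 31.3 (3.32 to 16) and Mir221 at 293 (31.9 to 130). Replicate 8 of the cKO held the piRNA loci in 18 qE1 at 694 (others up to 291) and 8 qC5 at 154 (5.9 to 63.3). In Defb41 testis sperm, control replicate 4 held Mir10a at 4220 (874 to 1140) and Mir10b at 69200 (10500 to 12300).

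In Stra8 testis sperm, control replicate 1 held Mir375 at 6260 RPM (others 2930 to 3140) and Mir10a at 5660 (2740 to 3160), and control replicate 4 Mir93 at 460 (259 to 283). The piRNA locus in 18 qE1 was at 22400 in control replicate 2 (14800 to 15900), at 24200 in cKO replicate 1 (18400 to 19100) and, in cauda sperm, at 1120 in cKO replicate 2 (3030 to 3100). Control replicate 2 of Stra8 cauda sperm held Mir141 at 5340 (1360 to 1730), Mir10b at 120000 (56700 to 61100) and 25.2% miRNA reads (14.2 to 14.9). Mir20a was at 2.9 in cKO replicate 3 of cauda sperm (4.8 to 4.86), and tRNA at 58% in cKO replicate 4 (64.2 to 64.6). The piRNA share was 1.47% in cKO replicate 2 of Stra8 caput (0.462 to 0.591) and 0.816% in control replicate 4 of Stra8 cauda (0.295 to 0.482). In units of 1e6 reads, depth was 13.1 in control replicate 4 of Stra8 cauda sperm (8.89 to 9.56) and 38.7 in cKO replicate 4 of Stra8 testis sperm (5.51 to 8.22).

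In mRNA, Cst11 was at 0.74 TPM in cKO replicate 1 of Stra8 cauda and 0 in the other 3. Among libraries labelled caput control of the Defb41 line, replicate 1 held Lcn2 at 21700 (17500 to 18100), and among those labelled cauda cKO, replicate 3 held it at 934 (235 to 307). Among those labelled cauda control, replicate 2 held Crisp1 at 3.36 (0.58 to 0.71) and replicate 4 Mirlet7bhg at 173 (94.9 to 100).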

How the results depend on the processing

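The tests with library size from the class table, miRNAs alone scaled to the miRNA total, near-identical embryo pairs joined, class shares from the feature table or without single libraries, single libraries left out in Defb41 cauda sperm and Stra8 caput small RNA, and all settings for the relation of effects were chosen after the data were seen. Of 407 called values of named genes, 384 kept their call with the replicate or set as a block and 0 turned direction. TMM kept 181 of 220 and turned 7, DESeq2 kept 213 of 220, centring 169 of 187, a pseudocount of 0.1 171 of 187, miRNA scaling 78 of 129, and set means 0 of 39. Of counts per comparison, 272 alternatives lay within 1.5 times the value reported and 88 did not. The 272 include alternatives with 0 calls where the reported count was 0 too, so they do not measure how stable the counts above 0 are. The causes of the changes below were not tested.

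DESeq2 called 260 features in Stra8 testis sperm, 149 in Stra8 cauda sperm, 57 in the Stra8 difference of effects, 101 in Defb41 testis sperm, 10 in Defb41 caput and 147 in Defb41 cauda. TMM called 1 in Defb41 cauda and 0 in Defb41 testis sperm (edgeR, 409 at an unadjusted p under 0.05; DESeq2 101). With TMM, Mir143 (0.20), Mir148b (0.96), Mir25 (0.10), Mir30e (0.91), Mir320 (0.04), Mir34c (0.03) and Mirlet7i (0.12) turned to higher between testis and cauda sperm of Stra8 controls. Scaled to the miRNA total, Mir100 (0.17) and Mir148a (0.29) turned in Stra8 testis sperm. Camera with an estimated correlation called 3 of 338 lists against 68. Centring on the median gene gave 58 genes in Stra8 caput mRNA, 24 in Defb41 morulae with control RNA against control, 11 in Stra8 testis sperm morulae and 1 at their 4-cell stage. Set means gave 0 genes with limma in these 3 embryo comparisons and in miRNA against control RNA (281, 534, 549 and 665 at an unadjusted p under 0.05), where fewer values enter.

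Without a filter, 1.5e2 features (39 higher, 106 lower) passed in Stra8 cauda sperm, 47 genes in Stra8 caput mRNA and 12 in Stra8 testis sperm morulae. Without a series term, 96 passed in Defb41 cauda sperm and 7 in Stra8 cauda; series 2 alone gave 14 and 1, and series 1 alone 0 in Stra8 cauda (edgeR, 53 at an unadjusted p under 0.05), with fewer libraries. A pseudocount of 0.1 gave 40 genes in Stra8 caput mRNA and 6 in Defb41 morulae of miRNA against control. The block gave 322 and 295 genes in Stra8 caput and cauda mRNA, and, where numbers did not pair all samples, 152 in Stra8 cauda sperm, 274 in Stra8 testis sperm morulae, 79 and 324 in Defb41 morulae of miRNA against control RNA and against control, and 0 in Defb41 cauda (edgeR, 163 at an unadjusted p under 0.05; DESeq2 147 without the block); it moved no other count by more than 1.5 times. Of 100 splits within sets, 5 called as many as the 79 (highest other 875) and 1 as many as the 324 (highest other 261). Own numbers correlated best for 3 of 4 numbers in Stra8 cauda sperm and Stra8 testis sperm morulae, 2 of 4 in these Defb41 morulae and 0 of 3 in Defb41 cauda, a hint from the data alone.

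Leaving out single libraries gave 218 to 310 calls in Defb41 cauda sperm, where 17 of 22 named features stayed called, 0 in Stra8 caput small RNA (edgeR, 67 to 157 at an unadjusted p under 0.05), 94 (without cKO replicate 3) to 210 (cKO replicate 2) calls in Stra8 testis sperm, 13 (cKO replicate 1) to 134 (control replicate 2) in Stra8 cauda sperm, 14 to 37 (control replicate 4) in Stra8 cauda, 11 (control replicate 2) to 86 (cKO replicate 4) in Defb41 testis sperm, 0 to 1 (control replicate 2) in Defb41 caput, 0 (any library but control replicate 1) to 163 (control replicate 1) in Defb41 cauda, 1 (cKO replicate 3) to 193 (control replicate 2) in Stra8 caput mRNA and 0 to 1 (control replicate 3 or cKO replicate 3) in Stra8 cauda mRNA. In Defb41 cauda sperm, the repeat family RLTR13D1:ERV2 ranged from −0.32 (without cKO replicate 6) to 2.92 (control replicate 1). Mir1983 between sperm of Defb41 controls ranged from −0.45 (without cauda sperm replicate 4) to 2.58 (testis sperm replicate 1). Leaving out embryo sets gave 0 (set 1) to 7 (set 2) at the Stra8 testis sperm 4-cell stage and 1 (set 3) to 60 (set 2) in its morulae. In Defb41 morulae it gave 0 (set 3) to 21 with control RNA against control, 0 (set 3 or 4) to 183 (set 2) with miRNA against control RNA, and 0 to 134 (set 3) with miRNA against control. The relation of effects at the Defb41 4-cell stage ranged from −0.65 (without set 3, p = 0.0348 against the simulations) to −0.44 (without set 2). Depth of mRNA and embryo libraries is not known from TPM, and 6.16e5 reads in 1 library limit Defb41 caput small RNA.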

Other observations

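The tests with splits within embryo sets and with near-identical embryos joined were chosen after the results had been seen. In the libraries labelled Defb41 caput cKO, further genes of the distal epididymis were higher than in those labelled caput control: Ly6f rose from 4.00 ± 1.41 to 3220 ± 184 TPM, and Ltf, the iron-binding lactotransferrin, and Serpina1f rose by 10.39 and 8.11 on the log2 scale. The steroid reductases Srd5a1 and Srd5a2 fell by 2.20 and 2.08. In the libraries labelled cauda cKO, the basal cell keratin Krt14 fell from 375 ± 34.1 to 83.4 ± 30.7, and the interferon genes Irf7 and Isg15 by 1.56 and 1.80. As the labels of these libraries are in doubt, these values describe segments as much as genotypes.

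Between testis and cauda sperm of Stra8 controls, Mir10b rose from 29800 ± 9330 to 74000 ± 30900 RPM and Mirlet7c-2 from 325 ± 28.1 to 1130 ± 274, while the rRNA fragments of 5.8S fell from 24000 ± 3630 to 1710 ± 341. Mir200a and Mir451a changed by 3.85 and −3.60 in Defb41 controls.

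One small RNA library, with a title and a genotype that disagree, entered no group; it held 6.83e6 reads, of which 62.4% were miRNA, 23.8% rRNA, 10.4% tRNA and 1.08% piRNA. Among Defb41 embryos, 7 pairs had nearly identical profiles (r = 0.992 to 0.996, where the next highest were 0.957 at the 4-cell stage and 0.983 in morulae), and in 1 of them the labels name different groups. With pairs joined, 10 genes passed in morulae with control RNA against control and 12 with miRNA against control RNA.

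Other splits of the same samples were counted for each comparison, the real split included. In Stra8 testis sperm 1 of 35 splits called as many features as the real 161 (highest other 4). In Stra8 cauda sperm it was 1 of 35 (61, highest other 18), and for the Stra8 difference of effects 1 of 100 (37, other 17). These shares are under 0.05, the limit set beforehand as counting against chance, without adjustment over comparisons. The same holds for the transit of Stra8 and Defb41 controls, each 1 of 35 (856, other 0, and 812, other 1). It holds for mRNA of the Defb41 labels with 1 of 35 each (6042, other 1, and 3099, other 37). Defb41 cauda had 1 of 35 (71, other 0), but leaving out a single library could give 0 calls there. In Stra8 cauda 2 of 100 splits called as many (20, other 20). Defb41 cauda sperm had 1 of 100 (267, other 228) and the Defb41 difference 1 of 100 (314, other 283). In these 3 comparisons another split came near the real count or equalled it, so chance is not firmly excluded. In embryos, splits that ignore the sets gave 1 of 100 for Defb41 morulae with control RNA against control (15, other 1). They gave 2 of 100 for miRNA against control RNA (14, other 39). For Stra8 testis sperm morulae they gave 1 of 100 (22, other 2) and for their 4-cell stage 2 of 100 (2, other 3). Exchanging embryos only within sets gave 1 of 100 for control RNA against control (15, other 1). It gave the same for Stra8 testis sperm morulae (22, other 1) and their 4-cell stage (2, other 1, or 2 of 100 and other 3 with the block). These splits exchange single embryos, and the labels do not name the fathers, so they do not cover differences between fathers. On means per set 0 genes passed in these comparisons. For miRNA against control RNA, 7 of 100 splits within sets called as many as the real 14, so chance is not excluded. The highest other count of 907 pointed to a structure of the samples within sets. The same caution applies to the 4 genes shared with opposite direction in that comparison.

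Chance cannot be excluded for Defb41 testis sperm, where 2 of 35 splits called as many as the real 31 and one called 858, which points to a structure of the samples. With 3 libraries per group the 10 splits are too few, for Stra8 caput mRNA (1 of 10; 97, other 1) and for Defb41 caput (10 of 10; 0, other 319). Where the real count was 0, every split is as large by construction, which says nothing about chance: 100 of 100 in Stra8 caput (other 706), 35 of 35 in Stra8 cauda mRNA (other 72), 100 of 100 in each Defb41 4-cell comparison (other 1), in Defb41 morulae with miRNA against control (other 7), at the Stra8 cauda sperm 4-cell stage (other 1594) and in its morulae (other 5). The counts of 706, 319, 72 and 1594 point to a structure of the samples. At the Stra8 cauda sperm 4-cell stage sets are dates, deviations of a set were shared by both genotypes (r = 0.694 to 0.967), and 0 genes passed limma with the set as a block (773 at an unadjusted p under 0.05). In splits that part every pair, the highest other count was 0 in Stra8 caput mRNA, and in Stra8 cauda mRNA 0, or 3 with the block. With 4 such splits in caput and 8 in cauda, the real one included, no share under 0.05 is possible, so they cannot exclude chance.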
